A study of Arabidopsis thaliana with 12 samples.

How the data were processed

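The only sample analysed was 1 nanopore library of 3-week-old CENH3-OX seedlings, prepared from high molecular weight DNA with a ligation kit, per the labels' protocols. The 11 CENH3 chromatin immunoprecipitation samples were mapped to their groups from the labels and not analysed here. The authors deposited 3 tables for this library, 1 for each of the CG, CHG and CHH contexts, without headers. Each line holds a cytosine's chromosome, position and strand, the summed probabilities of the unmethylated and the methylated state, the number of methylated, unmethylated and total calls, the methylated fraction and the 5-base context. The deposited counts of methylated and unmethylated calls are raw counts per cytosine, and added up to the total in every line. The deposited fraction equalled methylated calls over total calls, within rounding, in every line. The modification caller, the aligner and the genome build were not given in the sources used here. Bowtie2 2.4.4 and bedtools 2.26.0 appear in the submitters' processing notes, without a role for this library.

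The tables listed 5 nuclear chromosomes, the plastid and the mitochondrial genome. The chromosome lengths they implied differed from the assembly of the gene table given (TAIR10.1), so no coordinates were taken from that table, and it served only for locus tags, symbols and the chromosome of a gene. Coordinates are 1-based in the build of the files. Since no genome of that build was given, chromosome sequence was rebuilt from the overlapping 5-base contexts. This recovered 88.0 to 94.5% of bases without a conflict. The planned classes, lists and profiles of annotated genes needed an annotation of this build and were not run. Tiles of 1 kb took the place of genes, a choice made after seeing the data.

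A methylation level is the number of methylated calls over all calls, pooled over cytosines with a coverage of at least 4. This minimum, the satellite and region rules and the tests of regions and subcontexts were set before the data were examined. The comparisons within arrays, of dyads by region, of reverse transcriptase loci and of rRNA repeats were added afterwards. Wilson intervals at 95% confidence were computed with scipy 1.17.1 (Python 3.11.15, numpy 2.4.6). They cover counting error only, because calls of 1 read are not independent. Satellite sequence was found as 12-base words of a 178 bp consensus taken from general knowledge. A window of 10 kb with at least 10% matching bases was satellite, windows up to 100 kb apart were joined, and the longest run was the array of the chromosome. The pericentromere was 2 Mb on each side, and the rest was arms. Non-satellite stretches inside arrays were at least 1 kb long. Protein and rRNA query sequences also came from general knowledge and were matched to the rebuilt sequence with BLAST 2.17.0. Loci joined matches of at least 85% identity covering at least 40% of the query, so a gene's identity rests on this match. AG, FLC, FT and CENH3 each matched the chromosome of their symbol in the gene table. Of the rule fixed for named genes, the part on CENH3 was followed, and the parts that rank annotated genes were not run. The other genes named were picked after the data had been seen, because their protein sequences were at hand, and a ubiquitin query gave no locus under this rule. Reverse transcriptase matches of at least 80 residues were ATHILA-type at 60% identity or more to an ATHILA sequence. A copy of the mitochondrial genome was located by matching the mitochondrial sequence.

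Regions were compared with a two-sided exact sign-flip permutation test over the 5 chromosomes, which cannot go below 0.0625, with Benjamini-Hochberg adjustment. Loci were compared with two-sided permutation tests of means with 100000 resamples. The class and level code was tested on simulated data. Of 1000 simulated tiles at a depth of 21, modelled on arms and pericentromere, 100% were classed correctly. At a depth of 3, modelled on the arrays, 916 of 1000 tiles could be classed and 99.8% of those were correct. The simulated CHG levels lay far from the class threshold of 10%. In the real arrays 2662 of 12330 tiles could be classed, with median CHG levels of 5.10% and 15.9% in the classes below and above it. The simulation therefore does not show how well array tiles were classed. Alternatives covered the coverage minimum, the definition of the level, the strand, high coverage, the background, the width of the regions, the class thresholds and the omission of each chromosome.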

Results

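DNA methylation was measured along the genome of Arabidopsis seedlings labelled as overexpressing CENH3 (CENH3-OX), the histone H3 variant that marks centromeric nucleosomes. The series names 12 samples, of which 11 were CENH3 chromatin immunoprecipitation libraries of 2-week-old seedlings, with 2 wild-type, 1 ddm1, 1 Tal1(WT), 3 Tal1(ddm1) and 4 CENH3-OX samples. They were not analysed here. The remaining sample was 1 nanopore library of 3-week-old CENH3-OX seedlings, with methylation calls at single cytosines in CG, CHG and CHH contexts, where H stands for A, C or T. With 1 library there was no biological replicate and no comparison with wild type. Each comparison below was made within this library, and the SD over the 5 nuclear chromosomes describes the spread along the genome only.

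The nuclear chromosomes held 1006991531 calls, and the median nuclear cytosine was covered by 21 calls. The plastid genome had a median coverage of 2094 and served as the background, because plastid DNA carries little or no cytosine methylation. The label of the line was examined first at the CENH3 gene itself (AT1G01370, HTR12), located by matching its protein sequence. The match lay on chromosome 1 from 147632 to 149256, in 9 aligned coding segments that covered 100% of the protein at 95.6% identity. Coverage was 22.5 ± 2.03 calls (SD over 276 cytosines) in the coding segments and 22.5 ± 1.91 (SD over 341 cytosines) between them. The coding segments thus had 0.996 times the coverage of the introns and 1.02 times the median of the chromosome arms. The gene stood at the 59.3th percentile of 61026 arm windows of its size, of which the central 95% ranged from 14.4 to 29.5 calls. No excess of DNA reads over the gene was detectable at this depth, and expression of CENH3 was not measured. Reads of a copy inserted elsewhere need not be placed on this gene, and the aligner is not known. Coverage here therefore does not show whether the plants carry an extra copy. The gene itself was nearly unmethylated, with a CG level of 1.81% (95% Wilson interval 1.22 to 2.67%), against 2.36% in the plastid genome.

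**Figure D1:**
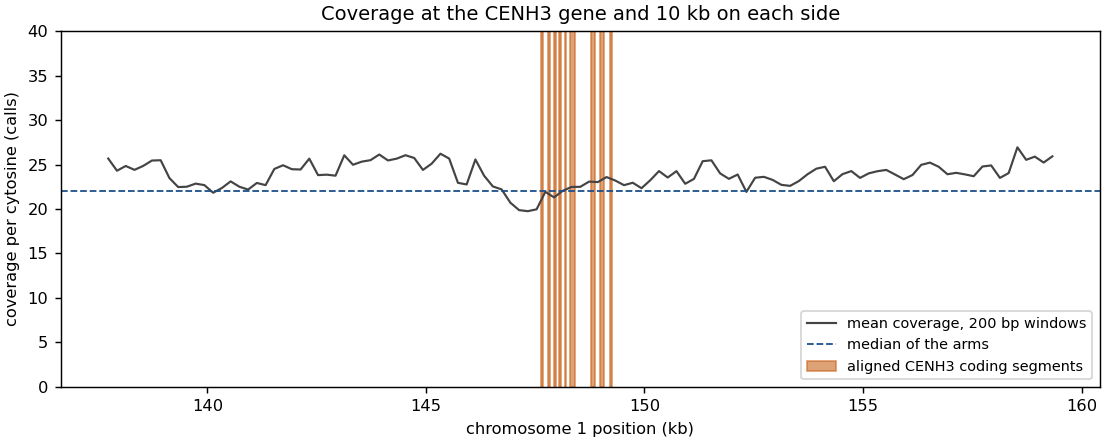
Mean coverage per cytosine (calls) in 200 bp windows along chromosome 1 (kb) at the CENH3 gene and 10 kb on each side. Orange bars mark the 9 aligned coding segments, which had 1.02 times the median of the arms (dashed line).

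Over the nuclear genome, 27.7% of CG calls, 8.51% of CHG calls and 1.98% of CHH calls were methylated. The corresponding plastid levels were 2.36%, 0.834% and 0.615%. The nuclear levels were therefore 11.7, 10.2 and 3.22 times the plastid levels of the same library. The plastid level was not a floor for nuclear calls. Tiles of 1 kb with CG and CHG levels under 10%, 50.3% of the classed nuclear tiles, had median CG, CHG and CHH levels of 1.80%, 0.613% and 0.434%. Each of these lay below the plastid level. Over the 5 chromosomes the mean was 27.7% ± 3.26 (SD, n = 5) in CG, 8.61% ± 1.69 (SD, n = 5) in CHG and 2.00% ± 0.164 (SD, n = 5) in CHH context. Wilson intervals around the pooled levels were narrow, for instance 27.68 to 27.70% in CG context, and cover counting error only.

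The next comparison asked how methylation was distributed around the centromeres, where CENH3 resides. Arrays of the centromeric satellite repeat were located on each chromosome from the sequence context in the files. They spanned 14840001 to 17130000 on chromosome 1 and 3820001 to 6170000 on chromosome 2. On chromosomes 3, 4 and 5 they spanned 13590001 to 15740000, 4200001 to 6980000 and 11790001 to 14550000. CG methylation was high in the arrays, at 79.6% ± 1.66 (SD, n = 5), against 20.8% ± 4.88 in the arms. CHG methylation behaved differently. It was 13.3% ± 4.003 in the arrays, 27.6% ± 7.22 in the 2 Mb of pericentromere on each side, and 5.42% ± 2.03 in the arms. Levels are pooled over calls. Non-satellite stretches inside the arrays had a median CHG coverage of 12, against 3 in the satellite, and so weighed more than by their length. The array CHG level was highest on chromosome 5, at 19.0%, which held the most such sequence, 524 kb. CHH methylation was 3.20% ± 0.539 in the arrays, 4.96% ± 1.16 in the pericentromere and 1.42% ± 0.213 in the arms.

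CG levels in the arrays exceeded those of the arms by 58.8 percentage points, and the pericentromere exceeded the arms by 44.5 points, in 5 of 5 chromosomes each. CHG levels in the arrays lay below the pericentromere by 14.3 points in 5 of 5 chromosomes (difference −14.3 ± 8.52, SD). All of these had p = 0.063 in a two-sided exact sign-flip permutation test over chromosomes, adjusted p = 0.0703 over 9 comparisons. With 5 chromosomes this is the smallest p the test allows, so no region difference could pass 0.05. For CHH the arrays lay below the pericentromere in 4 of 5 chromosomes (difference −1.76 points, exact permutation p = 0.125). Chromosome 2 stood apart in the pericentromere, with a CG level of 36.2%. It holds a copy of mitochondrial sequence from 3360614 to 3730451, which had 10.3 times the coverage of the arms and a CG level of 12.85%. A comparison without this copy and the 45S rRNA gene ends was added after seeing the data. The pericentromere then had 72.9% ± 2.86 CG, 30.9% ± 0.909 CHG and 5.41% ± 0.269 CHH methylation. The arms, which hold the 45S ends, then had 18.2% ± 1.37 CG, 4.43% ± 0.797 CHG and 1.34% ± 0.131 CHH methylation. The CG excess of the arrays over the pericentromere was then 6.61 points in place of 14.3, and the CHH difference was −2.21 points in 5 of 5 chromosomes. Values in the arrays rest on thin coverage. The median was 3 calls for CG cytosines, and 41.8% of the listed CG cytosines reached the minimum of 4.

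**Figure D2:**
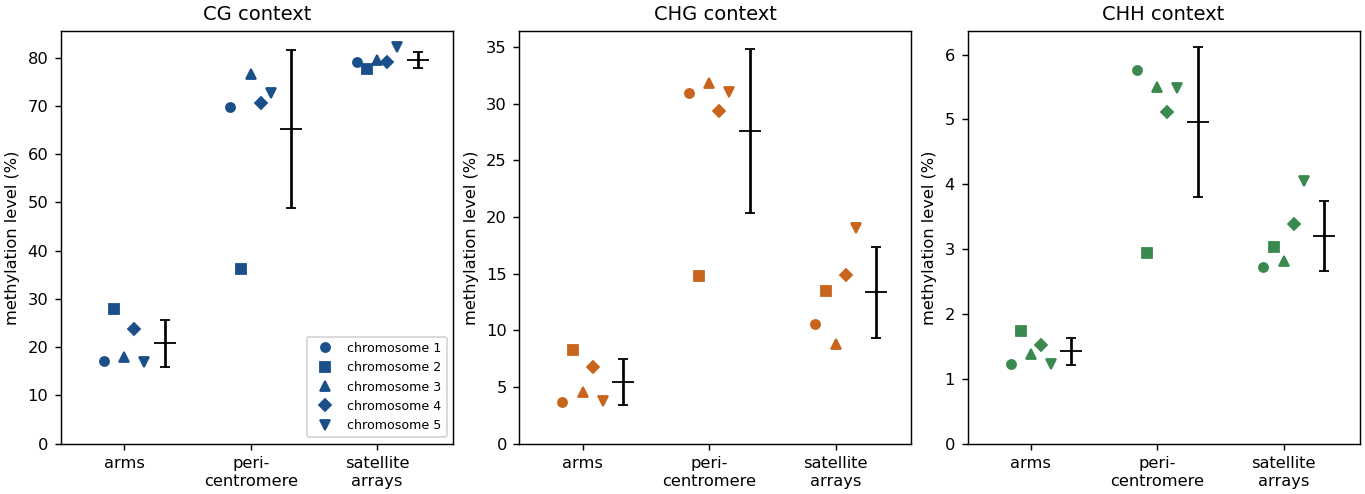
Methylation level (%) in the arms, the pericentromere and the satellite arrays in CG, CHG and CHH context. Each symbol is 1 of the 5 chromosomes and the black bars show the mean ± SD. CHG levels peak in the pericentromere (27.6%) and are lower in the arrays (13.3%), and the low pericentromeric square is chromosome 2.

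**Figure D3:**
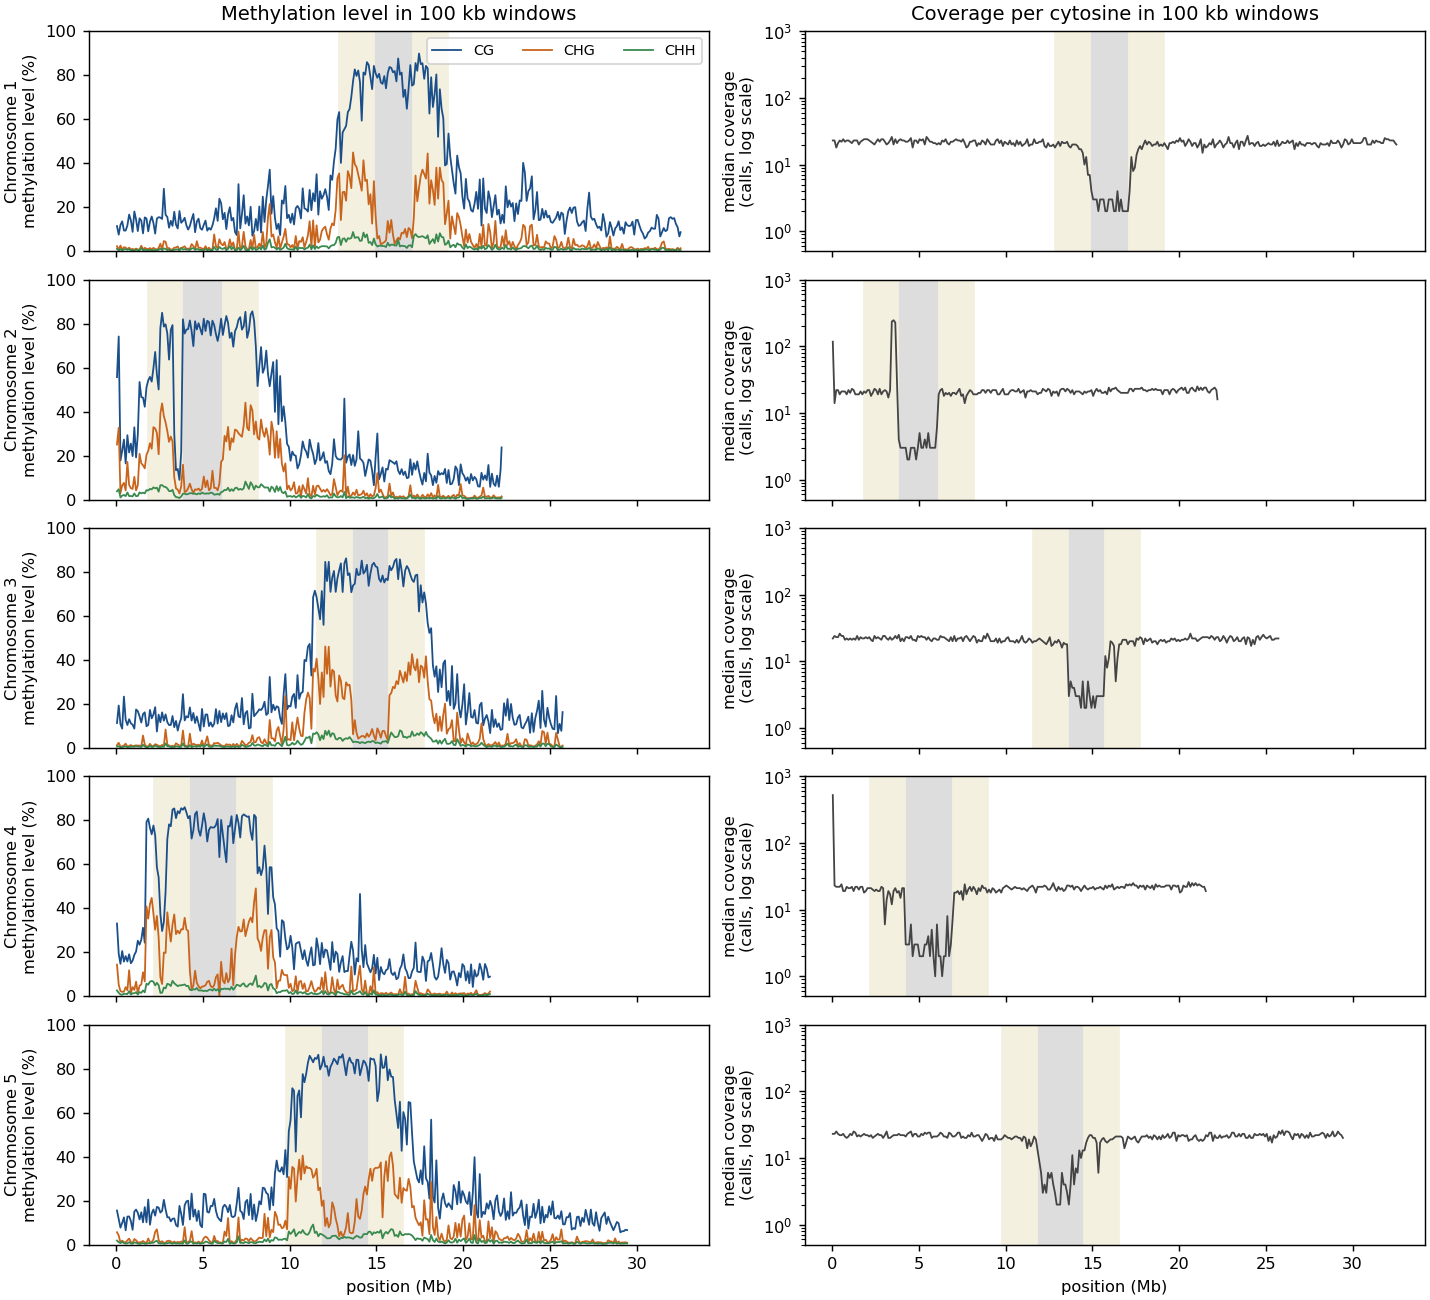
Methylation level (%, left) and median coverage per cytosine (calls, log scale, right) in 100 kb windows along the 5 chromosomes (Mb). Grey marks the satellite arrays and beige the 2 Mb on each side. CG methylation stays high across the arrays, where coverage is low. CHG methylation there, pooled over calls, is on average below the pericentromere and above the arms. The satellite itself had 6.60% ± 0.992 CHG methylation, near the 5.42% ± 2.03 of the arms, and the non-satellite stretches 17.2% ± 3.68.

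Inside the arrays, satellite repeats and other sequence differed in non-CG methylation. The arrays held 160 stretches of at least 1 kb without satellite, 1156 kb in all, of which 58 lay on chromosome 5 and 65 on chromosome 4. CHG methylation was 6.60% ± 0.992 (SD, n = 5) in the satellite and 17.2% ± 3.68 in these stretches. CHH methylation was 2.99% ± 0.363 and 3.84% ± 0.606. Both were lower in the satellite in 5 of 5 chromosomes (exact permutation p = 0.063, adjusted p = 0.0938 over 3 contexts). CG methylation was 78.6% ± 1.78 in the satellite and 81.2% ± 2.36 in the stretches, lower in the satellite in 4 of 5 chromosomes (exact permutation p = 0.125).

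Plant non-CG methyltransferases differ in the bases they prefer after the cytosine, so levels were compared by triplet. In the pericentromere and arrays together, CCG cytosines had 16.2% methylation and CAG and CTG cytosines 30.04%, a difference of −13.9 points ± 2.87 (SD, n = 5). CAA and CTA cytosines had 11.9%, against 2.21% in the other CHH triplets, a difference of 9.65 points ± 1.86. Both held in 5 of 5 chromosomes (exact permutation p = 0.063). The triplets were also compared within the arrays, after seeing the data. CAG methylation was 9.75% ± 1.74 in the satellite and 18.3% ± 3.84 in the other stretches. CTG methylation was 8.13% and 18.2%, and CCG methylation 5.39% and 11.4%. Each was lower in the satellite in 5 of 5 chromosomes, so the lower CHG level was present within each CHG triplet. CCG gave most satellite CHG calls, 189423 against 50945 for CAG and 43445 for CTG. In the stretches these were 108274, 291463 and 297516, so triplet composition also entered the pooled CHG difference. CAA methylation was 9.99% ± 0.715 in the satellite and 9.83% ± 1.92 in the stretches. This difference of 0.154 points ± 1.47 went the same way in 3 of 5 chromosomes. CTA methylation was 4.67% ± 0.881 in the satellite and 11.1% ± 2.13 in the stretches, a difference of −6.45 points ± 1.27 in 5 of 5 chromosomes (exact permutation p = 0.063, adjusted p = 0.0833 over 12 triplets). CAC, CAT, CCA, CTC and CTT were also lower in the satellite in 5 of 5 chromosomes, with the same p, whereas CCC and CCT, like CAA, did not go the same way in each chromosome.

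**Figure D4:**
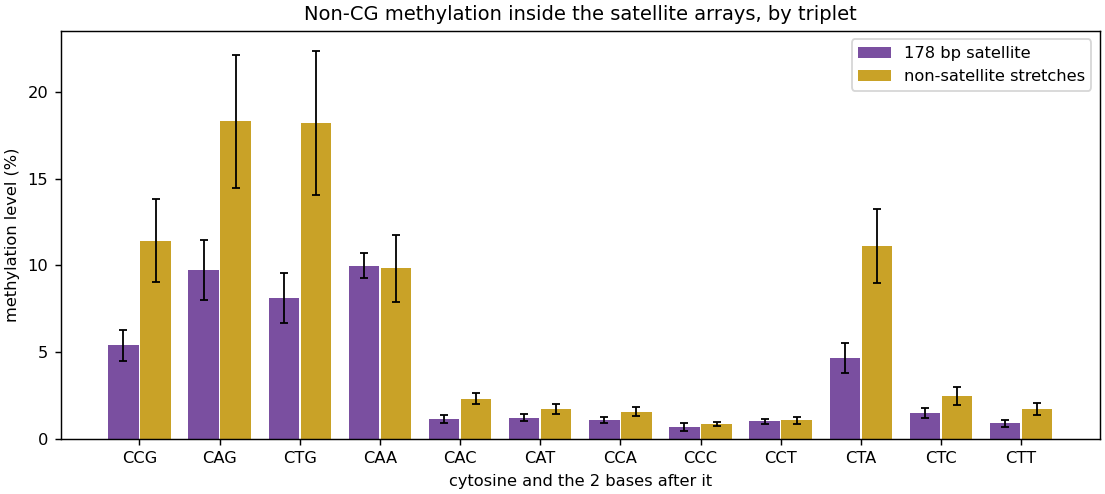
Methylation level (%) of CHG and CHH cytosines inside the satellite arrays by the 2 bases that follow, in satellite and in non-satellite stretches. Bars are means over 5 chromosomes and whiskers the SD. CAA is similar in both (9.99% and 9.83%), whereas the CHG triplets and 6 of the 9 CHH triplets are lower in the satellite in 5 of 5 chromosomes.

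Reverse transcriptase sequences were used to find retrotransposons, the class of element this study is about. Matches numbered 99 for ATHILA-type elements, the Gypsy family that resides in and around Arabidopsis centromeres, 180 for other Gypsy-type and 272 for Copia-type elements. ATHILA-type matches lay mostly in the pericentromere, with 85 there, 12 in the arrays and 2 in the arms. Copia-type matches numbered 145 in the arms, 125 in the pericentromere and 2 in the arrays. ATHILA-type loci in the arrays had a mean CHG level of 17.5% ± 7.94 (SD, n = 12 loci), against 35.1% ± 10.4 (SD, n = 77 loci) in the pericentromere. This difference of −17.6 points had an adjusted p of 4.5e-05 in a two-sided permutation test with 100000 resamples, over 9 comparisons. CHH levels were 4.59% ± 1.35 and 6.82% ± 2.66 (adjusted p = 0.011, permutation test), and CG levels were 78.8% ± 4.75 and 80.7% ± 5.43 (adjusted p = 0.29, permutation test). Of the 12 array loci, 11 lay on chromosome 5. Within chromosome 5 alone, a test added for this reason after seeing the data, CHG levels were 18.1% ± 8.07 in 11 array loci and 33.2% ± 10.6 in 17 pericentromeric loci (adjusted p = 0.00171, permutation test), and the CHH difference did not pass (adjusted p = 0.165, permutation test). Other Gypsy-type loci had less CHG methylation in the pericentromere (39.5% ± 14.03, n = 139 loci) than in the arms (49.5% ± 14.3, n = 40 loci; adjusted p = 0.00031, permutation test). Their CHH levels were 7.80% ± 3.60 and 11.3% ± 4.28 (adjusted p = 4.5e-05, permutation test), and their CG levels 85.8% ± 7.82 and 85.5% ± 12.4 (adjusted p = 0.85, permutation test). CHH methylation of Copia-type loci was 6.55% ± 3.76 in the pericentromere (n = 118 loci) and 9.12% ± 5.50 in the arms (n = 142 loci; adjusted p = 0.00012, permutation test). CG methylation of Copia-type loci went the other way, with 76.6% ± 20.1 in the pericentromere and 68.4% ± 30.3 in the arms (adjusted p = 0.018, permutation test). Their CHG levels, 35.6% ± 18.1 and 41.2% ± 24.6, did not pass (adjusted p = 0.053, permutation test). Loci of 1 library are not biological replicates. The tests treat loci as independent, which related elements on shared chromosomes need not be, so these p-values describe the loci of this library only.

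**Figure D5:**
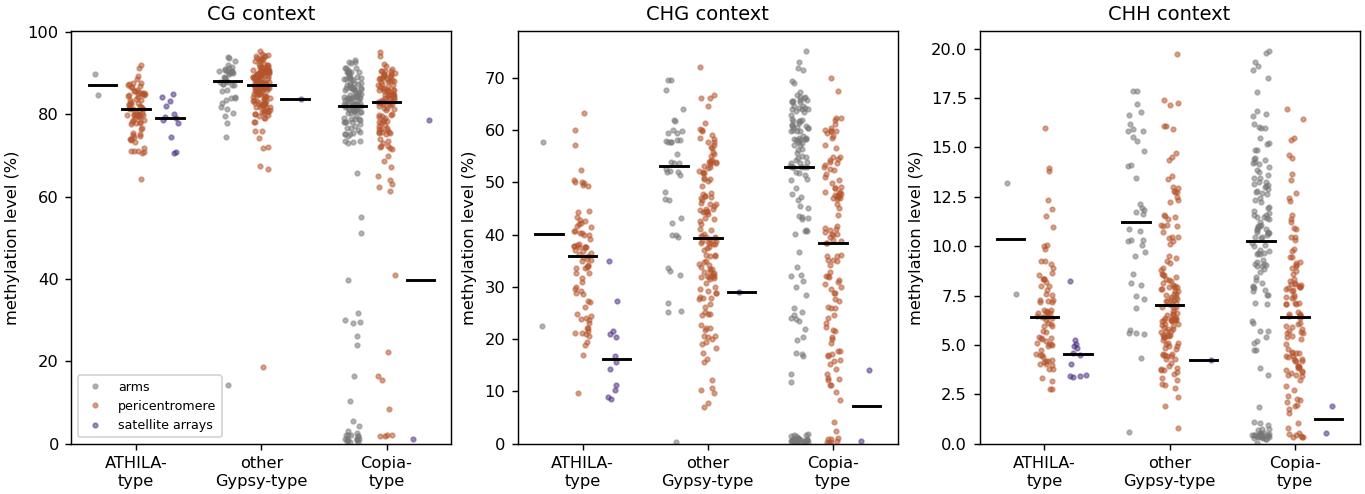
Methylation level (%) of reverse transcriptase loci in CG, CHG and CHH context, by element class and chromosome region. Each point is 1 locus with at least 5 covered cytosines per context and black bars are medians. ATHILA-type loci in the arrays have a median CHG level of 16.1%, against 35.8% in the pericentromere.

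Both strands of symmetric sites were compared at a coverage of at least 10. CG levels of the paired cytosines correlated with a Spearman rho of 0.767 over 2690236 dyads, and 4.33% of the methylated dyads passed 50% on 1 strand alone. Within regions rho was lower, at 0.639 in the arms, 0.615 in the pericentromere and 0.272 in the arrays. In the arrays 94.2% of CG dyads passed 50% on both strands, against 19.0% in the arms and 79.9% in the pericentromere. Methylated CG dyads with 1 strand alone made up 5.51% in the arms, 2.83% in the pericentromere and 3.84% in the arrays. At a coverage of at least 5 these were 5.89%, 3.15% and 6.18%. The lower CG rho in the arrays is therefore not read as weaker strand symmetry. For CHG dyads rho was 0.666 over 2426109 dyads, with 0.418 in the arms, 0.886 in the pericentromere and 0.626 in the arrays. Of the methylated CHG dyads 31.2% passed on 1 strand alone. Dyads of 1 library are not independent replicates. The share was 35.8% in the pericentromere and 24.2% in the arms. In the satellite arrays, where 13447 dyads reached this coverage, methylated or not, it was 68.1%. At a coverage of at least 5 it was 72.1% in the arrays (of 24636 dyads) and 36.5% in the pericentromere. At 20 only 53 array dyads remained, methylated or not, too few to compare. Inside the arrays the median CHG coverage was 3 in the satellite and 12 in non-satellite stretches, so array dyads at a coverage of 10 may lie mainly in the latter. Where levels are low and depth is near the minimum, counting error alone can put 1 strand over 50%. The share therefore does not establish strand asymmetry in the arrays.

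Sequence tiles of 1 kb were classed by level, in place of the planned genes. Of 98624 classed tiles in the arms, 59.99% were low in CG and CHG, 28.6% had CG methylation of at least 10% and CHG methylation under 10%, the pattern of gene body methylation, and 11.4% had CHG methylation of at least 10%. In the pericentromere 78.5% of 19529 tiles had CHG methylation. In the arrays 57.9% of 2662 classed tiles fell in the class with CG of at least 10% and CHG under 10%, of 12330 tiles listed. Their median CHG and CHH levels were 5.10% and 2.57%, above the 0.872% and 0.452% of this class in the arms. Tiles were not linked to genes, so neither set is shown to be gene body methylation. Among classed tiles, CHH levels of at least 10% occurred in 3.78% of arm tiles, 10.8% of pericentromeric tiles and 0.263% of array tiles. In the arrays, 34.7% of satellite CG cytosines reached the coverage minimum, against 92.0% in the non-satellite stretches. Classed array tiles may therefore over-represent those stretches, and their shares do not describe the arrays as a whole.

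A few well-known genes, picked after the data had been seen because their protein sequences were at hand, were located by protein match, and all lay in the arms. The floral regulators AG on chromosome 4 (13367841 to 13372081), FLC on chromosome 5 (3178965 to 3184550) and FT on chromosome 1 (26433875 to 26436048), known Polycomb targets, had CG levels of 1.41% (0.997 to 2.00%), 1.45% (1.14 to 1.83%) and 1.87% (1.203 to 2.91%). Histone genes were as low, with CG levels of 0.576 to 2.61% over 12 H3 loci and 0.871 to 2.21% over 8 H4 loci. The plastid CG level was 2.36%. The 7 actin family loci ranged widely, from 1.24 to 63.9% CG. The highest lay on chromosome 1 from 20358781 to 20360025 and had a CHG level of 0.976% and a CHH level of 0.514%. CG levels of 3.37 to 20.7% were found over 4 loci of the Rubisco small subunit, and of 0.868 to 11.4% over 4 loci of elongation factor 1-alpha. CHG levels stayed at or below 1.76% at each of these loci.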

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

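The test that compares 3 contexts was chosen only after the result was seen. The other tests were written once the pattern was known, before their own values were seen.

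The mitochondrial genome, which the comparisons above do not use, gave a CG level of 8.46% (95% Wilson interval 8.410 to 8.503%), above the 2.36% of the plastid genome in the same library. Its CHG and CHH levels were 2.93% and 0.942%. A sequence-dependent background of the caller was predicted to spread thinly over most cytosines. Instead, 2.91% of mitochondrial CG cytosines with a coverage of 10 or more reached 50% methylated calls, against 0.0216% in the plastid. This argues against a thinly spread background as the whole cause. A background concentrated at particular sequences could also give such cytosines, so the test does not exclude it. The plastid also had a higher median CG coverage, 1931.5 against 22 in the mitochondrial genome. Reads of nuclear copies remain a candidate source. The assembled copy on chromosome 2 holds 97.9% of the mitochondrial genome, had a median coverage of 226 and a CG level of 12.85%, while the mitochondrial genome had a coverage of 25, so reads of both origins may be placed on either.

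Sequence without a copy in the assembled nuclear chromosomes was expected to stay near the plastid level if only misplaced nuclear reads were the cause. The only such 1 kb tile had a CG level of 18.7% at a coverage of 224. Taken as written in advance, this value counts against misplaced nuclear reads as the cause. The bound was read differently once the value was known, because it assumed that the assembled sequence holds every nuclear copy, and because it rests on 1 tile. It is therefore left open here. The excess over the plastid in this tile, divided by the excess in the 200 kb of chromosome 2 before the copy, gave a share of nuclear reads of 21.3% from CG, 21.3% from CHG and 22.3% from CHH calls. The highest was 1.05 times the lowest, and at that coverage the share equals 2.21 nuclear copies. In 13 tiles with a copy of part of their sequence, also at a coverage of 224, the shares were 17.1%, 17.5% and 21.5%, a ratio of 1.26 and 1.90 copies. On the chromosome 2 copy they were 13.7%, 13.9% and 11.9%, a ratio of 1.16 and 1.35 copies, and in the 352 tiles with a whole copy 6.45%, 6.72% and 7.33%, a ratio of 1.14 and 0.0745 copies at their coverage of 24. A mixture of unmethylated mitochondrial reads and heterochromatic nuclear reads of copies outside the assembled sequence may account for such similar shares. The number of copies differed between these parts and is not settled. This remains a hypothesis, and no biological explanation was tested.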

How the results depend on the processing

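No paired analysis was possible because files of only 1 library were analysed here, so no groups with shared replicate numbers could be compared. The 9 region differences kept their direction under each of 17 alternatives, and the 2 subcontext differences under each of 5. No region difference can pass 0.05 with 5 chromosomes, so these say only that directions held. The size of the subcontext differences depended on the region. CCG minus CAG and CTG was −13.85 points in pericentromere and arrays together, −9.12 in the arrays alone and −1.63 in the arms. CAA and CTA minus the other CHH triplets was 9.65, 7.66 and 2.03 points. Among regions, the CG excess of the pericentromere over the arms, 44.5 points, ranged from 38.18 to 54.73, the latter without the mitochondrial copy and the 45S ends. The CHG difference between arrays and pericentromere, −14.26 points, ranged from −19.18 (mean of per-site frequencies) to −10.33 (pericentromere of 3 Mb). The CG excess of arrays over pericentromere, 14.3 points, moved by over 2 times. It was 7.10 points with the mean of per-site frequencies, 6.73 without coverage over 2 times the median and 22.5 with a pericentromere of 3 Mb. Leaving out a chromosome gave 7.55 (without chromosome 2) to 17.2 points, and leaving out the mitochondrial copy and the 45S ends, an alternative added after seeing the data, gave 6.61.

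Nuclear levels moved under most settings. The CG level was 27.88% at a minimum coverage of 1, 27.19% at 10, 29.62% as the mean of per-site frequencies and 30.03% from summed probabilities. It was 27.02% without high coverage, 27.46% on the forward and 27.92% on the reverse strand, 25.94% with the plastid level removed and 27.05% without the copies. The CHG level was 8.51% at a minimum of 1, as in the report, 8.46% at 10, 8.91% per site, 8.98% from probabilities, 8.13% without high coverage, 8.41% forward, 8.61% reverse, 7.75% with the plastid level removed and 8.14% without the copies. The CHH level was 1.99% at a minimum of 1, 1.95% at 10, 2.20% per site, 2.59% from probabilities, 1.96% without high coverage, 1.95% forward, 2.00% reverse, 1.37% with the plastid level removed and 1.97% without the copies. Leaving out each chromosome gave 26.82 to 28.98% in CG, 8.03 to 9.12% in CHG and 1.94 to 2.05% in CHH context.

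Methylated CG dyads with 1 strand alone made up 4.71% at a coverage of 5 and 3.71% at 20, and CHG dyads 32.14% and 27.91%. Of 51 alternative tile counts, 50 stayed within 1.5 times the main count. Counts without 1 chromosome fall by its share by construction, so this bound tests little for them. Tiles with CHG methylation fell from 27697 to 17842 when 30 covered cytosines were required, which by construction classes fewer tiles. With tiles of 500 bp and 2 kb, chosen after seeing the data, their share was 21.03% and 23.86%, against 22.9%. Tiles with CG methylation alone made up 23.44% and 32.78%, against 26.7%, and low tiles 55.53% and 43.37%, against 50.3%. The alternatives on whole genes and on matching of gene lists were not run, since no gene annotation of this build was used. The cause of other shifts was untested.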

Other observations

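The descriptions of rRNA repeats and array borders, and the values by stretch length and by chromosome, were chosen only after the data had been seen. The 2 tests of array coverage were written once the low coverage was known, before their own values were seen.

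The rRNA gene repeats were methylated on each chromosome where they were matched. The 45S repeats at the start of chromosome 2 (10 units matched, 20923 to 113873) had a CG level of 55.9% and a CHG level of 25.2% at a median coverage of 93. Those at the start of chromosome 4 (9 units, 5518 to 86342) had 32.99% and 14.5% at a coverage of 633. With an arm median of 22, these coverages exceed what the assembled units alone would give, and the chromosome from which these reads came is not known, so the 2 clusters are not compared. The 5S units, pooled within each chromosome, were heavily methylated on chromosomes 3, 4 and 5. Their CG levels were 84.98%, 84.1% and 85.7% and their CHG levels 36.2%, 41.5% and 38.9%, at median coverages of 7, 20 and 18.

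Levels were followed across the borders of the arrays in bins of 50 kb. Over 10 borders, the mean CHG level was 26.0% ± 6.65 (SD) in the 50 kb outside and 17.3% ± 6.73 in the first 50 kb inside. In the next 2 bins inside it was 11.03% ± 7.80 (9 borders) and 9.50% ± 7.64. Mean CG levels in these 4 bins were 79.04% ± 6.47, 81.02% ± 2.62, 75.2% ± 5.66 and 77.8% ± 4.43. Borders on the same chromosome are not independent, and no change across them was tested.

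Of 123 windows of 100 kb in the arrays, 118 had a median coverage under 0.5 times that of the arms. Ambiguous placement of reads in repeated sequence is a candidate explanation. It predicted at least 0.5 times the arm coverage in the non-satellite stretches and under 0.25 times in the satellite, and the values were 0.5 and 0.136. The bound written in advance was thus met exactly. It was read more strictly once the value was known, because 2 of 5 chromosomes reached it (0.409, 0.636, 0.364, 0.364 and 0.545 on chromosomes 1 to 5). The 48 stretches of at least 10 kb had a median of 11 calls. The 69 of 1 to 3 kb and the 43 of 3 to 10 kb had a median of 2, which is 0.0909 times the arms and under the 0.25 named in advance, for all stretches together, as counting against placement. Placement is left open here. Fewer satellite copies in these plants than in the assembly predicted no rise of coverage with the share of unique sequence (rho under 0.1). Over 1121 windows of 10 kb, Spearman's rho was −0.152, and by chromosome it ranged from −0.307 to 0.0592, under that bound. Uniqueness was scored on words of 100 bases, which need not set how whole reads are placed. Ambiguous placement could therefore also give no rise of coverage. The test does not separate the explanations, and no conclusion on satellite copies is drawn from it. Windows share a library and are not independent replicates. Neither explanation is excluded, and no biological explanation was tested.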
